A study of Mus musculus with 47 samples.

How the data were processed

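RNA of muscle stem cells (satellite cells, the resident stem cells of skeletal muscle) from 47 female C57B6/J mice was measured on Affymetrix expression arrays, 1 array per mouse. Per the labels, mice were put on a high-fat or a matched control diet at 8 weeks of age, fed freely for 7 weeks and sampled at 15 weeks. Collection took place at 6 zeitgeber times 4 h apart, written ZT0 to ZT20. The mice of both diets at a given time were all collected on a single day. Time of day and collection day are therefore confounded within each diet, whereas each contrast between diets at a time point lies within 1 day. Each of the 12 groups held 4 mice, except high-fat ZT16 with 3 mice here.

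Per the labels, cDNA was made and amplified from 25 ng of total RNA over 17 cycles, and 8 µg of cDNA was fragmented and labelled with biotin. The deposited values are log2 expression values per probe set, and the submitters' processing notes name robust multi-array averaging (RMA), which corrects background, equalises the arrays by quantiles and summarises probes. The version and settings of RMA are not given in the sources used here. In the deposited table the array medians lay between 5.86 and 5.94 on the log2 scale and values between 2.13 and 13.1. No 2 arrays were identical, and the correlation between arrays across the 10258 genes tested (chosen as given below) ranged from 0.942 to 0.988. Quantile methods set the overall level of all arrays alike, so differences are relative to the bulk of genes, and differences near the array's background (median of 3.89 over 23 non-specific control probe sets) are compressed. The number of arrays limits the precision.

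The table holds 45141 probe sets, of which 28898 carry 1 gene symbol in the platform annotation, 551 several and 15692 none. Symbols were updated through the gene identifier, which matched the reference gene table for 28689 probe sets. Probe sets with several or no symbols were named after no gene and not tested, and the 104 control probe sets were left out. For each of 17097 genes the probe set with the highest mean over all arrays was kept, and genes whose mean lay under the 40th percentile (5.80 on the log2 scale) were left out, which left 10258 genes. Of these, 5496 had more than 1 probe set.

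Tests used R 4.3.3 with limma 3.58.1 (lmFit and eBayes with an intensity trend in the variance), two-sided, with Benjamini-Hochberg adjustment over the 10258 genes and a threshold of 0.05 on the adjusted p. All adjusted p-values of genes are from limma. All mice entered each fit, so that groups share an estimate of the spread. For daily rhythms, a 24 h cosine and sine were fitted within each diet, with an F test of 2 coefficients. Amplitude is the distance from the fitted mean to the peak. Peak times are those of the fitted cosine, which can differ from the time point with the highest mean. For a difference in rhythm between diets, the time point entered as a 6-level factor with diet and its products with cosine and sine. For diet effects, the 12 group means were fitted, and the high-fat minus control difference was tested at each time, as the mean over the 6 times, and as an interaction F test of 5 coefficients. Values after ± are standard errors (SE) from limma unless SD is named, and the n behind them is 4 mice per group, 3 at high-fat ZT16, and 24 control and 23 high-fat mice for averages and rhythms.

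Before the data were examined, 31 gene lists were fixed, of pathways and of markers of cell types. The 28 with at least 3 tested genes were tested for diet shifts with camera at a preset correlation of 0.01 and again with an estimated correlation. Over-representation among rhythmic genes was tested with Fisher's exact test, one-sided, with the tested genes as background, and genes are not independent replicates there. The rhythm of a list's mean was tested by 100000 permutations of the mice over times within a diet, and the clock list's mean amplitude and peak time were compared between diets by 100000 permutations of diet within times. The smallest p such permutations can give is 1e-05. These permutations treat mice, not days, as exchangeable.

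Genes named in the text follow a rule fixed with the lists. For rhythms these are the clock list and the 12 largest other amplitudes, for rhythm differences and the interaction the 10 smallest p, for the average diet effect the 12 largest increases and decreases with the same sign at 5 or more times, for each time the 3 largest increases and decreases, and for each list up to 4 members with the smallest p. Differences of these genes at further times are given in places. The same-sign rule was not applied to list members, so their average differences can rest on few times.

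The models were tested on simulated data with 200 changed genes among 10258. An amplitude of 0.2 on the log2 scale was recovered for 40.0% (control) and 47.0% (high-fat) of the genes and one of 0.4 for 89.5% and 95.0%. Rhythm differences of 0.4 were recovered for 76.0% and average diet effects of 0.2 and 0.4 for 49.5% and 94.5%. Effects at single times of 0.5 were recovered for 44.0% (ZT16) to 57.0% (ZT8 and ZT12) and effects of 1 for 93.0% (ZT16) to 98.0% (ZT12). For the interaction, an effect of 0.5 at a time was recovered for 23.5% with 11.3% of the calls false, and an effect of 1 for 75.0% with 9.09% false, above the nominal rate. In the other settings the false share ran from 3.17% (rank test, amplitude 0.2) to 8.05% (control rhythms, amplitude 0.2), so some of these exceeded it too. Each setting was a single run with independent noise per gene and no day effect.

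Alternatives were no filter and a filter at the 60th percentile, all probe sets or the mean of a gene's probe sets, cyclic loess, centring of arrays on the median, array weights, no variance trend, the replicate number as a block, an F test over the time points, a rank test, each diet alone, the collection day as a random block, other forms of the rhythm and diet models, only the mice of a time point, and each mouse left out in turn.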

Results

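Gene expression was measured in muscle stem cells of mice on a control diet (24 mice) or a high-fat diet (23 mice), collected at ZT0, ZT4, ZT8, ZT12, ZT16 and ZT20, in order to compare the daily course of expression between the diets. ZT0 is by convention the time of lights on. Each group held 4 mice, and high-fat ZT16 held 3. Values are deposited log2 expression values from arrays, which have no read depth. The mean correlation of an array with the others of its group lay between 0.969 and 0.987, and the median SD within groups was 0.19 on the log2 scale over the 10258 genes tested.

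The circadian clock cycled in stem cells on both diets. On the control diet Npas2, a positive-arm clock factor, peaked at 22.1 ± 0.255 h with an amplitude of 0.64 ± 0.04. Its repressor Nr1d2 peaked at 8.62 ± 0.321 h with an amplitude of 0.77 ± 0.06. The output factor Dbp followed at 10.6 ± 0.355 h (0.86 ± 0.08). Later came Per3 at 12.9 ± 0.418 h (1.14 ± 0.12) and Per2, a period repressor, at 15.7 ± 0.304 h (1.01 ± 0.08). On the high-fat diet the same genes peaked at 21.3 ± 0.338 h (Npas2, 0.51 ± 0.04), 8.95 ± 0.321 h (Nr1d2, 0.80 ± 0.06), 10.2 ± 0.336 h (Dbp, 0.95 ± 0.08), 12.2 ± 0.473 h (Per3, 1.04 ± 0.13) and 15.9 ± 0.331 h (Per2, 0.93 ± 0.08). Of the 20 clock genes tested, 15 were rhythmic on the control diet (17 adjusted over the list alone) and 16 on the high-fat diet (18 adjusted over the list alone). Arntl, the partner of Clock and Npas2, had an amplitude of 0.69 ± 0.21 on the control diet, short of the threshold (adjusted p = 0.0615), and of 1.18 ± 0.21 on the high-fat diet (adjusted p = 0.000391). Its difference in rhythm between the diets did not pass (adjusted p = 0.249). Clock, Cry1, Cry2, Rora, Tef, Hlf, Nfil3, Bhlhe41 and Usp2 passed on both diets. Csnk1e passed on the control diet only, Bhlhe40 on the high-fat diet only, and Per1, Ciart and Csnk1d on neither. The mean amplitude of the clock list was 0.43 on the control and 0.46 on the high-fat diet, a difference of 0.03 (permutation p = 0.329). The mean peak time shift was -0.0776 h (permutation p = 0.788). In that mean each gene was weighted by the product of its amplitudes on the diets, so genes of large amplitude count most. The permutations had an SD of 0.03 for the amplitude and of 0.279 h for the peak time, and an amplitude change or shift of that size would not have been detected.

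**Figure D1:**
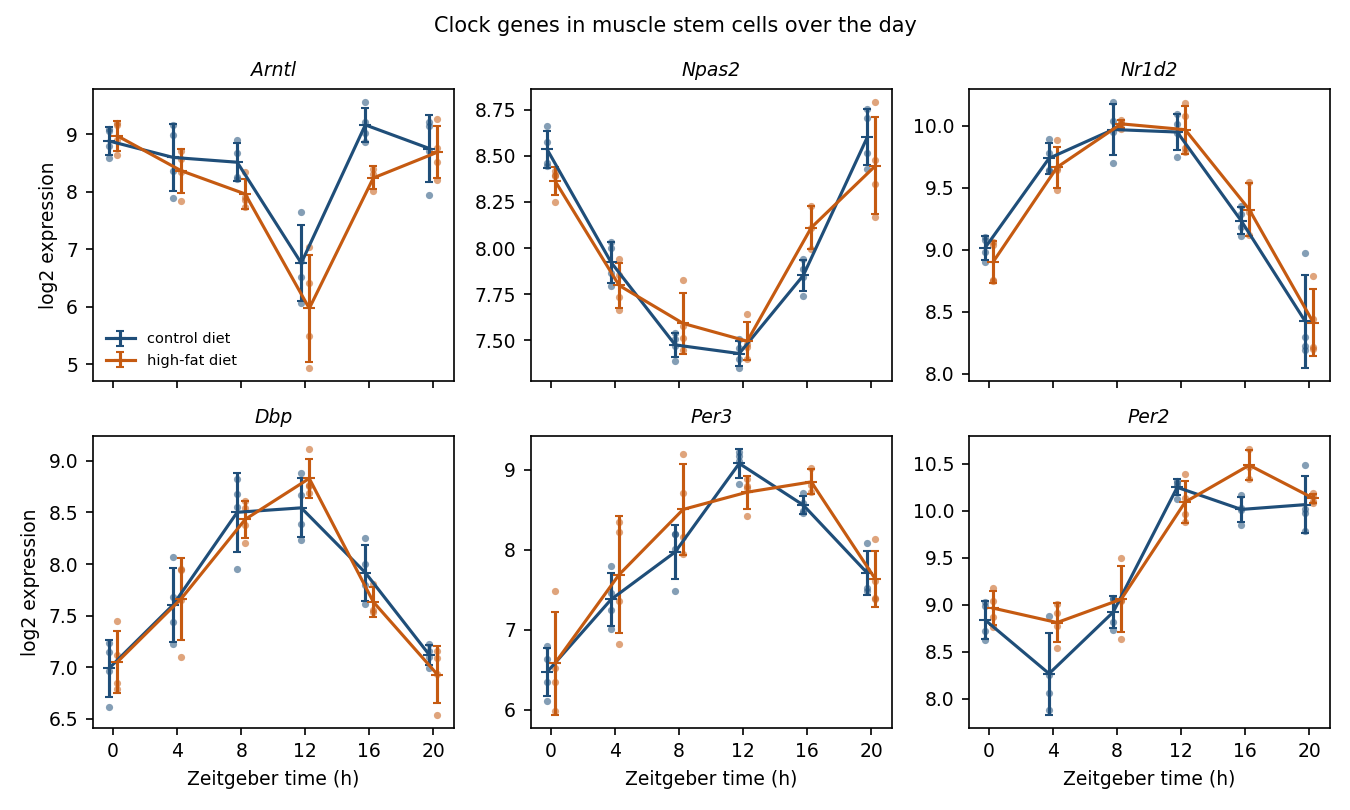
Log2 expression of 6 clock genes against zeitgeber time in hours; points are mice, lines join group means and bars are SD (n = 4 mice per group, 3 at high-fat ZT16). The curves of the diets run broadly alike, with fitted control peaks of Npas2 at 22.1 h, Nr1d2 at 8.62 h, Dbp at 10.6 h and Per2 at 15.7 h. Mean Arntl of the high-fat mice was lower at ZT8 (7.96 against 8.51), ZT12 (5.97 against 6.76) and ZT16 (8.24 against 9.16). It was lower by less at ZT4 (8.36 against 8.59) and ZT20 (8.68 against 8.75), and not lower at ZT0 (8.97 against 8.88).

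Beyond the clock, no list was tested against differences between collection days, so list rhythms are not separated from them. Cholesterol synthesis followed a 24 h curve on both diets. Its list mean had an amplitude of 0.50 with a fitted peak at 4.88 h on the control diet (adjusted permutation p = 0.00028) and of 0.44 with a fitted peak at 4.04 h on the high-fat diet (adjusted permutation p = 7e-05). On the control diet 11 of its 16 genes were rhythmic (12 adjusted over the list alone; odds ratio 18.8, adjusted p = 6.29e-07). Among them were Idi1, an isoprenoid enzyme, with an amplitude of 1.26 ± 0.18, Nsdhl with 0.93 ± 0.12, Cyp51 with 0.77 ± 0.09 and the sterol sensor Insig1 with 0.57 ± 0.05. On the high-fat diet 10 of the 16 passed (12 adjusted over the list alone). Glucocorticoid-responsive genes had fitted peaks of the list mean at 14.6 h on the control and at 13.8 h on the high-fat diet. The observed list mean was highest at ZT12 on the control diet (9.99 ± 0.08, SD, n = 4) and at ZT16 on the high-fat diet (10.41 ± 0.08, SD, n = 3). Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, peaked at 15.5 ± 0.458 h with an amplitude of 0.96 ± 0.12 on the control diet and at 14.1 ± 0.383 h with 1.16 ± 0.12 on the high-fat diet. Zbtb16 had amplitudes of 0.91 ± 0.17 and 1.14 ± 0.18. Of the 14 genes of that list, 5 were rhythmic on the control diet (8 adjusted over the list alone) and 11 on the high-fat diet (11 adjusted over the list alone). The largest amplitude on either diet belonged to Sphk2, a sphingosine kinase, with 1.43 ± 0.09 on the control and 1.52 ± 0.09 on the high-fat diet and peaks at 10.5 h. Other genes with large amplitudes were Actc1 (1.24 ± 0.34), Acta1 (0.91 ± 0.19), Stard4 (0.90 ± 0.13), Akr1c14 (0.87 ± 0.23), Sqle (0.84 ± 0.12), Wee1 (0.81 ± 0.17) and Cdh4 (0.81 ± 0.13) on the control diet. Those on the high-fat diet were Ugt1a6a (0.99 ± 0.20), Wee1 (0.98 ± 0.17), Cyp51 (0.93 ± 0.09), Thrsp (0.93 ± 0.12), Fkbp5 (0.88 ± 0.13), Olfm2 (0.88 ± 0.23), Tfdp2 (0.87 ± 0.13) and D230025D16Rik (0.86 ± 0.18). Acta1 and Actc1 are muscle actins, and the mature myofibre list mean had an amplitude of 0.13 on the control diet (adjusted permutation p = 0.0527) and of 0.09 on the high-fat diet (adjusted permutation p = 0.17).

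On the high-fat diet, mitochondrial and protein turnover genes were over-represented among rhythmic genes. Of 69 oxidative phosphorylation genes 33 were rhythmic (43 adjusted over the list alone; odds ratio 4.58, adjusted p = 3.27e-08). Examples are Atp5b with an amplitude of 0.26 ± 0.04 and Ndufs3 with 0.35 ± 0.06, and the fitted peak of the list mean was at 6.29 h. Of 35 proteasome genes 16 were rhythmic (21 adjusted over the list alone; adjusted p = 0.000364), including Psmb3 with 0.27 ± 0.04. The lists for unfolded protein and integrated stress response (10 of 19, 11 adjusted over the list alone, adjusted p = 0.0018), satellite cell identity and quiescence (11 of 24, 12 adjusted over the list alone, adjusted p = 0.00312) and fatty acid synthesis (8 of 14, 9 adjusted over the list alone, adjusted p = 0.00297) passed too. So did the clock, cholesterol (adjusted p = 0.000364) and glucocorticoid lists (adjusted p = 6.34e-06). On the control diet the clock and cholesterol lists were over-represented, a number of 2 that rose to between 4 and 8 without any 1 of 25 of the 47 mice (8 without control ZT20 replicate 4). There, 10 of 69 oxidative phosphorylation genes were rhythmic (13 adjusted over the list alone, adjusted p = 0.402) and 6 of 35 proteasome genes (6 adjusted over the list alone, adjusted p = 0.4). Whether a list's share of rhythmic genes differs between diets was not tested. The list means with a rhythm on the control diet numbered 5, namely clock, cholesterol, glucocorticoid, unfolded protein (adjusted permutation p = 0.0265) and proteasome (adjusted permutation p = 0.00343). On the high-fat diet they numbered 10, with satellite cell identity (adjusted permutation p = 9.33e-05), oxidative phosphorylation (7e-05), immediate early genes (0.00217), heat shock (0.0202) and insulin and FOXO response (0.0203) in addition. On the control diet fatty acid oxidation, fatty acid synthesis and oxidative phosphorylation lay just over the threshold, each with an adjusted permutation p of 0.0527. Without control ZT0 replicate 1 or control ZT12 replicate 3, the control number was 8 each.

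In all, 1081 of 10258 genes (10.5%) were rhythmic on the control diet and 1731 (16.9%) on the high-fat diet, and 483 were rhythmic on both against 182 for independent lists (odds ratio 5.13). That expectation leaves out that the mice of both diets shared their collection days. Of the 483 genes, 310 (64.2%) had peaks within 2 h of each other and 12 had peaks over 6 h apart. Control peaks were most frequent between 6 and 10 h (314 genes, 29.0%) and high-fat peaks between 2 and 6 h (570 genes, 32.9%, against 213 genes or 19.7% on the control diet). The counts do not separate a daily course from day-to-day differences. Of the 60 orders in which the 6 days can be placed around the clock, 16 gave as many rhythmic genes as the true order on the control diet and 5 on the high-fat diet. With the day as a random block 289 and 580 genes passed. Without the ZT16 mice the high-fat count was 1062, an alternative chosen after seeing the data, and the control count was 1210.

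The rhythm itself differed between the diets for 216 genes, 138 with the larger amplitude on the high-fat and 78 on the control diet. Both diets were collected on the same days, so this contrast lies within days. Mag, a myelin protein gene of Schwann cells, had an amplitude of 0.13 ± 0.05 on the control and of 0.34 ± 0.05 on the high-fat diet (adjusted p = 0.000926). Xpo1, the main nuclear export receptor, peaked at 6.37 h on the control and at 22.9 h on the high-fat diet (0.46 ± 0.09 and 0.36 ± 0.09, adjusted p = 0.00516). The methyltransferase gene Ezh1 peaked at 21.8 and 15.6 h with amplitudes of 0.19 ± 0.05 and 0.38 ± 0.06 (adjusted p = 0.00828). Atxn2, Car5b, Enho, Anpep, Dixdc1, Emc3 and Ap1m1 followed with adjusted p-values from 0.00828 to 0.0105. Bhlhe41 was the only clock gene that differed, with peaks at 9.89 h on the control and 13.5 h on the high-fat diet and amplitudes of 0.40 ± 0.05 and 0.31 ± 0.05 (adjusted p = 0.023). The count depended on the model, with 22 genes for cosine and sine in place of the time factor, 105 with the replicate number as a block, 482 from contrasts of the 12 group means and 596 with array weights. It was 59 without high-fat ZT16 replicate 3, 102 without high-fat ZT16 replicate 1, 120 and 140 without control ZT16 replicates 4 and 3, 139 without control ZT4 replicate 3 and 142 without control ZT8 replicate 3.

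Averaged over the day, the high-fat diet went with higher expression of inflammatory and of some lipid-responsive genes. NF-kB target genes rose: Tnfaip3, a feedback inhibitor of NF-kB, by 0.56 ± 0.05, the apoptosis inhibitor gene Birc3 by 0.50 ± 0.05, the chemokine gene Cxcl1 by 0.57 ± 0.08 and Nfkb2 by 0.14 ± 0.04. Of the 11 genes of that list 6 rose and 0 fell (6 and 0 adjusted over the list alone; camera adjusted p = 4.9e-08). This was the only list that held with an estimated correlation (adjusted p = 0.000815). Angptl4, a lipase inhibitor and PPAR target, rose by 0.81 ± 0.08 (adjusted p = 9.05e-09), Cpt1a, which admits fatty acids to mitochondria, by 0.25 ± 0.06, and Pdk4 by 0.19 ± 0.04. The average of Cpt1a rests on its rises at ZT8 and ZT16, given below. The list of fatty acid oxidation and PPAR targets went both ways (5 rose and 2 fell of 24, 5 and 2 adjusted over the list alone, camera adjusted p = 0.308). In the fatty acid synthesis list the desaturase gene Scd1 (-0.19 ± 0.03), Elovl5 (-0.17 ± 0.04) and Fasn (-0.17 ± 0.04) fell (3 of 14 fell, 4 adjusted over the list alone, camera adjusted p = 0.333).

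Among oxidative phosphorylation genes 22 of 69 fell and 0 rose (40 fell adjusted over the list alone; camera adjusted p = 5.05e-14, adjusted p = 0.0906 with an estimated correlation). Among them were Ndufa9 (-0.28 ± 0.05) and Cox5a (-0.24 ± 0.05). Ribosomal protein genes fell slightly, 19 of 65 (29 adjusted over the list alone), such as Rpl29 (-0.09 ± 0.02) and Rpl35 (-0.10 ± 0.02; camera adjusted p = 5.47e-11, adjusted p = 0.158 with an estimated correlation). Of 35 proteasome genes 8 fell (13 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.000532, adjusted p = 0.156 with an estimated correlation). Of 16 glycolysis genes 5 fell and 1 rose (10 and 1 adjusted over the list alone; camera adjusted p = 0.00665, adjusted p = 0.0906 with an estimated correlation), with Pgk1 at -0.18 ± 0.04 and the regulator Pfkfb3 at 0.33 ± 0.05. The lists of autophagy and lysosome (4 of 21 fell, 6 adjusted over the list alone, camera adjusted p = 0.0172, adjusted p = 0.0906 with an estimated correlation) and antioxidant and NRF2 targets (3 of 17 fell and 1 rose, 6 and 1 adjusted over the list alone, camera adjusted p = 0.0218, adjusted p = 0.158 with an estimated correlation) were lower. With cyclic loess the antioxidant list no longer passed (adjusted p = 0.0795).

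Genes of satellite cell identity and quiescence rose, 10 of 24 (11 rose and 1 fell adjusted over the list alone; camera adjusted p = 3.71e-06, adjusted p = 0.0618 with an estimated correlation), such as the Notch effector gene Heyl by 0.18 ± 0.03, Foxo3 by 0.15 ± 0.03 and the growth arrest gene Gas1 by 0.26 ± 0.06. The average of Foxo3 rests largely on ZT16, and this gene was lower at ZT20, short of the threshold there. Myod1, the myogenic commitment factor (-0.28 ± 0.04), and Cdkn1a (-0.19 ± 0.04) fell. The list of commitment and differentiation did not pass (1 rose and 2 fell of 12, 1 and 3 adjusted over the list alone, camera adjusted p = 0.222). Extracellular matrix genes rose, 5 of 24 (7 adjusted over the list alone; camera adjusted p = 3.1e-05, adjusted p = 0.0906 with an estimated correlation), such as Col15a1 by 0.61 ± 0.13 and Lamb1 by 0.48 ± 0.11. At ZT4 the matrix list was lower instead. Markers of fibro-adipogenic cells and fibroblasts were higher alongside (2 of 8 rose, 4 adjusted over the list alone, camera adjusted p = 0.0344, adjusted p = 0.205 with an estimated correlation). Schwann cell markers were higher too (2 of 5 rose, 2 adjusted over the list alone, camera adjusted p = 0.0218, adjusted p = 0.205 with an estimated correlation), with Mbp up by 0.36 ± 0.09. Interferon response genes rose (5 of 12, 6 adjusted over the list alone; camera adjusted p = 0.00225, adjusted p = 0.0906 with an estimated correlation), such as Stat2 by 0.21 ± 0.06. Immediate early genes rose on average (4 rose and 2 fell of 21, 4 and 2 adjusted over the list alone, camera adjusted p = 0.0242, adjusted p = 0.432 with an estimated correlation), such as Jun by 0.17 ± 0.03. The immediate early list was not higher throughout the day, since it was lower at ZT0 and higher at ZT16.

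The other lists did not pass for the average: clock (camera adjusted p = 0.771), mature myofibre (0.324), endothelial (0.771), immune (0.988), smooth muscle and pericyte (0.392), cholesterol (0.771), glucocorticoid (0.771), insulin and FOXO (0.758), heat shock (0.324), unfolded protein (0.566), cell cycle (0.325) and DNA damage and p53 (0.392). Among these lists, and not among those that passed, median, mean and test differed in sign for clock, endothelial, fatty acid oxidation, glucocorticoid and insulin and FOXO. The adipocyte, erythroid and cold-inducible lists had too few tested genes for a test. The adipocyte gene Lipe rose by 0.18 ± 0.04 and Retn was at 0.00 ± 0.03. The erythroid genes Hba-a1 and Hba-a2 were at -0.32 ± 0.26 and -0.04 ± 0.03. The cold-inducible gene Cirbp was at 0.06 ± 0.08.

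In all, 1180 genes differed on average, 482 higher and 698 lower on the high-fat diet, with a median absolute log2 difference of 0.20 and 13 genes beyond 1.5-fold. The largest increases beside those named were in Scara5 (0.82 ± 0.16), Igsf10 (0.76 ± 0.11), Igfbp5 (0.67 ± 0.13), Klf1 (0.61 ± 0.13), Tmem255a (0.57 ± 0.11), Casp4 (0.56 ± 0.08), Kcna1 (0.52 ± 0.10) and H2-Q5 (0.50 ± 0.09). The largest decreases were in Akr1c14, a steroid-metabolising reductase (-1.04 ± 0.23), Gria1 (-0.84 ± 0.17), the hormone-responsive gene Greb1 (-0.70 ± 0.22), Olfm2 (-0.69 ± 0.18), Nifk (-0.65 ± 0.09), Slco2a1 (-0.63 ± 0.16), Grwd1 (-0.63 ± 0.15), Rad18 (-0.53 ± 0.08), Ppat (-0.53 ± 0.10), Rwdd4a (-0.52 ± 0.09), Aff3 (-0.50 ± 0.17) and Nol8 (-0.50 ± 0.09). The excess of lower genes depended on the scaling: with cyclic loess 607 were higher and 537 lower. Without the ZT16 mice 584 genes passed, of which 482 were among the 1180.

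At ZT0, lights on, 365 genes differed, 136 higher and 229 lower on the high-fat diet. Igfbp5 rose by 1.54 ± 0.30, Col15a1 by 1.30 ± 0.31 and Lix1 by 1.20 ± 0.26, and Gria1 (-1.65 ± 0.41), Slco2a1 (-1.42 ± 0.38) and Btbd11 (-1.23 ± 0.33) fell. Nuclear receptors of the immediate early list fell, such as Nr4a2 (-0.73 ± 0.11) and Nr4a1 (-0.47 ± 0.07). Of that list, 3 of 21 genes fell (7 adjusted over the list alone; camera adjusted p = 0.00362, adjusted p = 0.384 with an estimated correlation). Cholesterol genes were higher (2 of 16 rose, 5 adjusted over the list alone; camera adjusted p = 1.58e-05, adjusted p = 0.118 with an estimated correlation), such as Stard4 by 0.95 ± 0.22 and Fdps by 0.74 ± 0.19. Matrix genes were higher as well (4 of 24 rose, 5 adjusted over the list alone; camera adjusted p = 3.4e-06, adjusted p = 0.107 with an estimated correlation). Markers of fibro-adipogenic cells were higher beside them (0 of 8 rose, 1 adjusted over the list alone; camera adjusted p = 0.0465, adjusted p = 0.366 with an estimated correlation). NF-kB targets rose, 3 of 11 (3 adjusted over the list alone; camera adjusted p = 0.000537, adjusted p = 0.0713 with an estimated correlation). Ribosomal protein genes fell, 8 of 65 (16 adjusted over the list alone; camera adjusted p = 3.75e-07, adjusted p = 0.396 with an estimated correlation). Glucocorticoid-responsive genes were lower, with a median of -0.14 (2 of 14 fell, 4 adjusted over the list alone; camera adjusted p = 0.00946, adjusted p = 0.357 with an estimated correlation). The shares turned with the scaling, to 203 higher and 165 lower with cyclic loess. Counts were 194, 200 and 193 without control ZT0 replicates 1, 2 and 4 and 175, 223 and 122 without high-fat ZT0 replicates 1, 2 and 4. With the mice of ZT0 alone 86 genes passed.

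At ZT4 the diets differed least, in 32 genes (21 higher, 11 lower), and 1261 genes had an unadjusted p under 0.05. Cpt2, a mitochondrial carnitine transferase, rose by 0.85 ± 0.10 (adjusted p = 1.57e-06), and Bcorl1 by 0.97 ± 0.16, 4930456A14Rik by 0.95 ± 0.22 and Satb1 by 0.91 ± 0.21. Scd1 (-0.42 ± 0.08), 1700012D01Rik (-1.22 ± 0.26), Ift122 (-0.87 ± 0.21) and Ppifos (-0.77 ± 0.18) fell. Heat shock genes were higher (1 of 15 rose, 5 adjusted over the list alone; camera adjusted p = 0.000171, adjusted p = 0.127 with an estimated correlation), with Dnajb1 up by 0.28 ± 0.07. Cholesterol genes were lower (0 of 16 fell, 2 adjusted over the list alone; camera adjusted p = 0.000413, adjusted p = 0.39 with an estimated correlation). Matrix genes were lower too, with a median of -0.09 (0 of 24 fell, 2 adjusted over the list alone; camera adjusted p = 0.00261, adjusted p = 0.45 with an estimated correlation). The count was 10 and 16 without control ZT4 replicates 2 and 3 and 16 without high-fat ZT4 replicate 3. Again, 0 genes passed when limma was fitted to the mice of ZT4 alone (991 at an unadjusted p under 0.05).

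At ZT8, 183 genes differed, 78 higher and 105 lower (93 and 85 with cyclic loess, 87 and 86 with arrays centred on the median). Angptl4 rose by 1.09 ± 0.19, Cpt1a by 0.64 ± 0.14, D230025D16Rik by 1.59 ± 0.29 and Ppip5k1 by 1.30 ± 0.36. Scd1 (-0.53 ± 0.08), the arginine synthesis gene Ass1 (-1.20 ± 0.21), Fmo2 (-1.10 ± 0.30) and Xpo1 (-1.01 ± 0.18) fell. Matrix genes were higher (1 of 24 rose, 6 adjusted over the list alone; camera adjusted p = 1.15e-06, adjusted p = 0.121 with an estimated correlation), with Sparc up by 0.26 ± 0.06, as was the fibroblast marker Dpt by 0.35 ± 0.08, though its list did not pass (1 of 8 rose, 2 adjusted over the list alone, camera adjusted p = 0.174). Cholesterol genes were lower (0 of 16 fell, 5 adjusted over the list alone; camera adjusted p = 0.00273, adjusted p = 0.193 with an estimated correlation). Counts were 80 and 58 without control ZT8 replicates 1 and 3, 78, 120 and 91 without high-fat ZT8 replicates 2, 3 and 4, and 5 with the mice of ZT8 alone.

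At ZT12, lights off by convention, 88 genes differed, 48 higher and 40 lower (41 and 53 with arrays centred on the median). Smoc2 rose by 1.72 ± 0.44, Fmod, a matrix proteoglycan gene, by 1.39 ± 0.34 and Gjb2 by 1.16 ± 0.22, and Lypla1 (-1.03 ± 0.27), Pcif1 (-1.02 ± 0.20) and 3110082I17Rik (-0.96 ± 0.22) fell. Smoc2 is a marker of fibro-adipogenic cells, whose list was higher (1 of 8 rose, 4 adjusted over the list alone; camera adjusted p = 0.00374, adjusted p = 0.197 with an estimated correlation). The Schwann cell genes Mbp and Mag rose by 1.07 ± 0.23 and 0.54 ± 0.10 (2 of 5, 2 adjusted over the list alone; camera adjusted p = 0.000282, adjusted p = 0.197 with an estimated correlation). Cholesterol genes were higher (0 of 16 rose, 5 adjusted over the list alone; camera adjusted p = 0.000744, adjusted p = 0.197 with an estimated correlation). The mean of the oxidative phosphorylation list was lower instead, at 9.47 ± 0.03 on the high-fat and 9.60 ± 0.06 on the control diet (SD, n = 4 each). Counts were 49, 24, 40 and 23 without control ZT12 replicates 1 to 4, 28, 16 and 57 without high-fat ZT12 replicates 1, 3 and 4. The count was 0 when limma was fitted to the mice of ZT12 alone (1363 at an unadjusted p under 0.05).

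At ZT16, in the dark phase, the diets differed most, in 1360 genes (629 higher, 731 lower; 729 and 658 with cyclic loess). Glucocorticoid-responsive genes rose together, 9 of 14 (11 adjusted over the list alone; camera adjusted p = 1.32e-10, adjusted p = 0.00182 with an estimated correlation), such as the chaperone gene Fkbp5 by 1.44 ± 0.19, Sesn1 by 1.16 ± 0.17, Tsc22d3 by 1.07 ± 0.19 and Cebpd by 0.72 ± 0.09. NF-kB targets rose, 5 of 11 (5 adjusted over the list alone; camera adjusted p = 1e-05, adjusted p = 0.0054 with an estimated correlation), with Tnfaip3 up by 1.51 ± 0.14 and Cxcl1 by 1.25 ± 0.22. Immediate early genes rose, 10 of 21 (12 adjusted over the list alone; camera adjusted p = 3.44e-08, adjusted p = 0.0457 with an estimated correlation), such as Btg2 by 0.54 ± 0.08 and Junb by 0.43 ± 0.08. The stress-induced gene Trp53inp1 rose by 1.61 ± 0.15, Foxo3 by 0.78 ± 0.07 and the glycolytic regulator Pfkfb3 by 1.32 ± 0.14. Lipid genes moved both ways: Angptl4 rose by 1.48 ± 0.21, Cpt1a by 0.99 ± 0.15 and Thrsp by 1.81 ± 0.27, whereas Idi1 (-1.37 ± 0.25) and Fasn (-0.52 ± 0.12) fell. Of 16 cholesterol genes 3 fell (7 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.0354, adjusted p = 0.335 with an estimated correlation).

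Oxidative phosphorylation genes fell at ZT16, 25 of 69 (28 adjusted over the list alone; camera adjusted p = 1.32e-10, adjusted p = 0.128 with an estimated correlation), such as Ndufb2 (-0.70 ± 0.15) and Cox5a (-0.59 ± 0.12). Proteasome genes fell, 9 of 35 (12 adjusted over the list alone; camera adjusted p = 8.09e-06, adjusted p = 0.074 with an estimated correlation), such as Psmb3 (-0.65 ± 0.09). Satellite cell genes rose, 6 of 24, and 1 fell (9 and 1 adjusted over the list alone; camera adjusted p = 0.000812, adjusted p = 0.128 with an estimated correlation), with Gas1 up by 1.04 ± 0.15, while Myod1 fell by 0.70 ± 0.10. Among markers of other cells, the myofibre genes Pvalb and Mylpf rose by 0.65 ± 0.14 and 0.52 ± 0.13, Gsn by 0.24 ± 0.06, Mag by 0.41 ± 0.11 and the adipocyte gene Lipe by 0.66 ± 0.11, though the lists of the 6 other cell types tested did not pass (camera adjusted p from 0.0705 to 0.389). The cold-inducible gene Cirbp rose by 1.01 ± 0.20. Scara5 (1.78 ± 0.43) and Klf1 (1.70 ± 0.34) completed the largest increases. The largest decreases were in Slc15a2 (-5.09 ± 1.14), Olfm2 (-2.34 ± 0.47) and Aff3 (-1.85 ± 0.44). The tested Slc15a2 probe set ranged from 4.04 to 11.3 between mice, and its lowest value lay near the background of 3.89, so the size of its decrease is imprecise. The other 2 probe sets of that gene averaged 5.16 and 4.52, under the filter at 5.80, and differed by -0.04 and 0.04, so the decrease rests on 1 probe set. The count was 598 without high-fat ZT16 replicate 3, 845 without high-fat ZT16 replicate 1 and 906 without control ZT16 replicate 4. All 1360 genes kept their sign in each of these, which is likely for genes called from largely the same mice.

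At ZT20, 84 genes differed, 31 higher and 53 lower. Glucocorticoid-responsive genes were lower on the high-fat diet: Tsc22d3 (-1.22 ± 0.18), Zbtb16 (-1.47 ± 0.26) and Ddit4 (-1.16 ± 0.23) fell, 3 of 14 in all (8 adjusted over the list alone; camera adjusted p = 3.62e-09, adjusted p = 0.00391 with an estimated correlation). Heat shock genes rose, 5 of 15 (5 adjusted over the list alone; camera adjusted p = 5.21e-06, adjusted p = 0.0232 with an estimated correlation), with Dnajb1 up by 0.36 ± 0.07 and Hspb1 by 0.33 ± 0.06. Gjb2 rose by 1.17 ± 0.22, Fam204a by 1.13 ± 0.24 and Tmem255a by 1.02 ± 0.26. Ebf1 (-1.66 ± 0.31) and the cell cycle inhibitor gene Cdkn1c (-1.47 ± 0.35) fell. Pericyte genes fell, such as Kcnj8 (-1.45 ± 0.32) and Pdgfrb (-0.86 ± 0.20; 2 of 7, 3 adjusted over the list alone; camera adjusted p = 0.00474, adjusted p = 0.292 with an estimated correlation). Endothelial genes were lower (0 of 7 fell, 0 adjusted over the list alone; camera adjusted p = 0.0085, adjusted p = 0.471 with an estimated correlation). Control ZT20 replicate 2 held high endothelial transcripts, with Pecam1 at 9.11 against a mean of 6.66 in the other 46 mice and Cdh5 at 9.57 against 6.86. Without it, a choice made after seeing the data, 41 genes passed, and the endothelial list did not (adjusted p = 0.927). The glucocorticoid list held with an estimated correlation (adjusted p = 0.00648) and the heat shock list passed (adjusted p = 0.000577) but not with an estimated correlation (adjusted p = 0.0938). Counts were 43 and 46 without control ZT20 replicates 1 and 3, 42 without high-fat ZT20 replicate 3 and 4 with the mice of ZT20 alone. With cyclic loess 40 genes were higher and 42 lower.

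**Figure D2:**
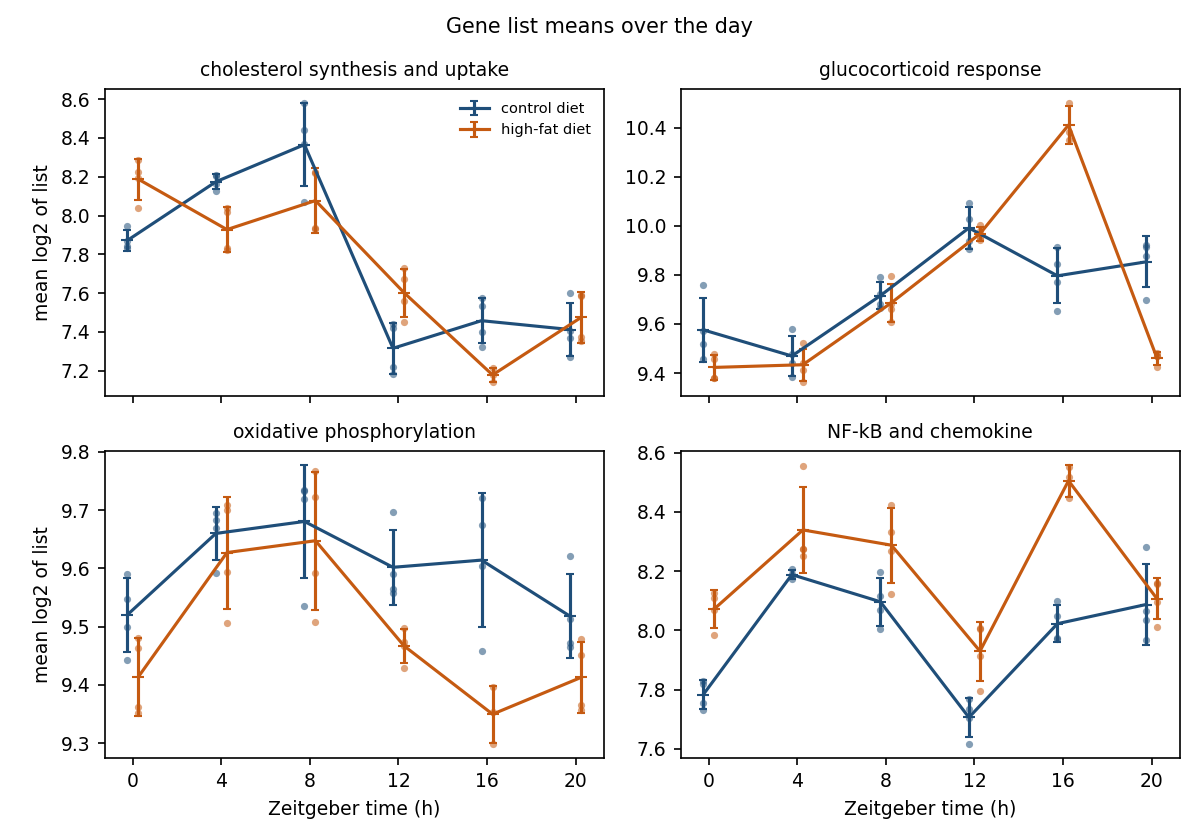
Mean log2 expression of the genes of 4 lists against zeitgeber time in hours; points are mice, lines join group means and bars are SD (n = 4 mice per group, 3 at high-fat ZT16). The glucocorticoid list of the high-fat mice lies above that of the controls at ZT16 (median difference of its genes 0.43) and below it at ZT20 (-0.21).

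The diet difference itself varied over the day for 1276 genes. Trp53inp1 had the smallest p (adjusted p = 1.21e-08): it rose by 1.61 ± 0.15 at ZT16 and fell by 0.73 ± 0.13 at ZT20. Foxo3 (adjusted p = 2.37e-07) rose by 0.78 ± 0.07 at ZT16 and was at -0.26 ± 0.07 at ZT20, short of the threshold there. Sash1 (adjusted p = 1.22e-06) rose by 0.70 ± 0.08 at ZT16 and fell by 0.37 ± 0.08 at ZT20, and Slc10a6 (adjusted p = 8.37e-06) rose by 1.22 ± 0.16 and fell by 0.82 ± 0.15. Tsc22d3 (adjusted p = 9.57e-06) changed sign between the same times. Txnip, a glucose-responsive inhibitor of thioredoxin (adjusted p = 1.01e-05), rose by 1.09 ± 0.13 at ZT16, Cyp2d22 by 1.02 ± 0.12 and Usp54 by 1.65 ± 0.20. The amino acid transporter gene Slc7a8 fell by 0.76 ± 0.16 at ZT0 and rose by 1.14 ± 0.17 at ZT16, and Rtn4rl2 fell by 0.85 ± 0.13 at ZT8 and rose by 0.57 ± 0.14 at ZT16. The count was 837 without high-fat ZT16 replicate 3, and simulated data gave false calls above the nominal rate for this test.

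**Figure D3:**
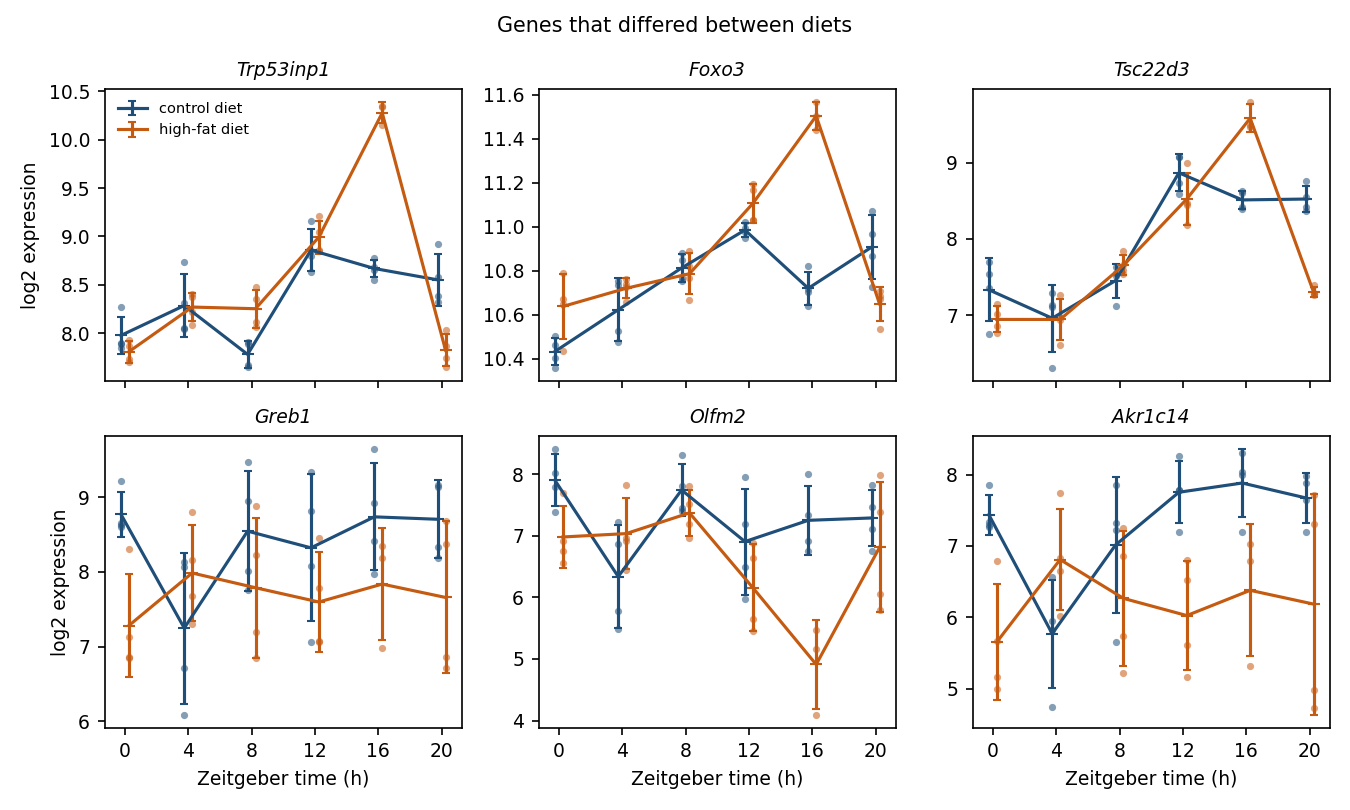
Log2 expression of 6 genes against zeitgeber time in hours; points are mice, lines join group means and bars are SD (n = 4 mice per group, 3 at high-fat ZT16). Trp53inp1, Foxo3 and Tsc22d3 lie higher in high-fat mice at ZT16 (by 1.61, 0.78 and 1.07), and Olfm2 lies lower there (-2.34).

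**Figure D4:**
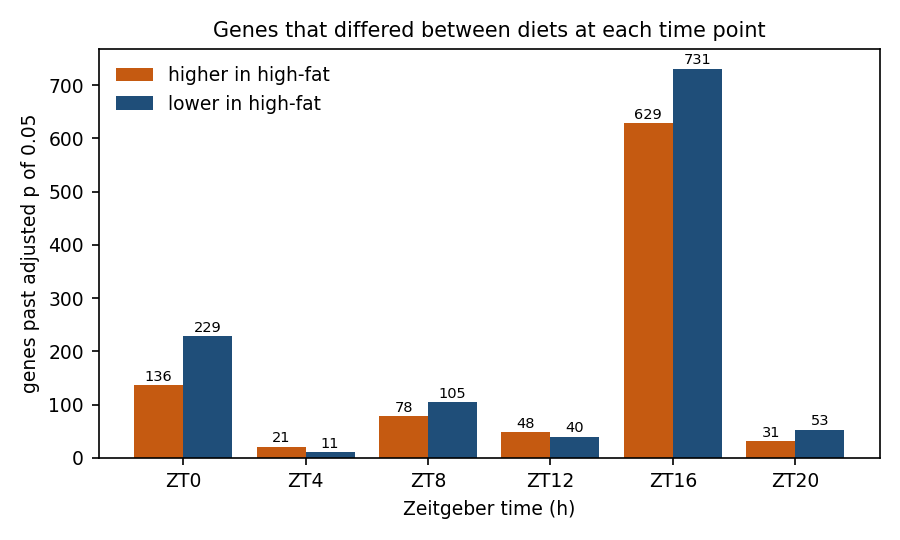
Number of genes past an adjusted p of 0.05 between diets at each zeitgeber time, as bars for genes higher and lower on the high-fat diet. The bars are highest at ZT16 (629 and 731) and lowest at ZT4 (21 and 11).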

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

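Tests chosen only after the result was seen were those of other cell types and of an earlier or sharper peak at ZT16, both tests of variation outside the 24 h curve, and all tests of the genes lower in high-fat mice.

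For 24 of 418 combinations of a group of 4 mice and a measure, 1 mouse lay apart from the other 3 by Dixon's test, and chance gives 1 in 20, or 20.9. The values are log2, with the range of the other 3 mice in parentheses. Control ZT20 replicate 2 had an endothelial list mean of 8.934 (6.845 to 7.071), the widest gap. Lower values were the median of all probe sets in high-fat ZT8 replicate 3 with 5.886 (5.896 to 5.897), the clock list in high-fat ZT4 replicate 1 with 8.46 (8.565 to 8.585), the myofibre list in control ZT8 replicate 4 with 6.556 (6.711 to 6.721), the endothelial list in high-fat ZT8 replicate 1 with 6.574 (6.888 to 6.93), and heat shock in high-fat ZT0 replicate 2 with 10.076 (10.225 to 10.233). Interferon response was lower in control ZT4 replicate 1 with 7.143 (7.236 to 7.248), extracellular matrix in the same mouse with 9.001 (9.267 to 9.281), antioxidant targets in control ZT12 replicate 3 with 9.376 (9.45 to 9.457) and oxidative phosphorylation in control ZT8 replicate 2 with 9.535 (9.718 to 9.735). Proteasome genes were lower in control ZT12 replicate 3 with 8.763 (8.802 to 8.809) and control ZT16 replicate 1 with 8.732 (8.84 to 8.848). The mean correlation with the other arrays of the group was 0.973 in control ZT4 replicate 4 (0.974 in the others).

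Higher values were satellite cell identity in control ZT16 replicate 2 with 10.123 (9.993 to 9.998), myogenic commitment in high-fat ZT4 replicate 2 with 8.099 (7.783 to 7.836), NF-kB targets in the same mouse with 8.554 (8.252 to 8.276), and fibro-adipogenic markers in control ZT8 replicate 3 with 9.152 (8.963 to 8.989). Smooth muscle markers were higher in control ZT20 replicate 1 with 9.519 (9.316 to 9.336), fatty acid synthesis in control ZT16 replicate 1 with 8.113 (8.028 to 8.043), insulin and FOXO response in high-fat ZT8 replicate 2 with 8.852 (8.705 to 8.726), heat shock in control ZT4 replicate 4 with 10.27 (10.184 to 10.194) and proteasome genes in control ZT20 replicate 4 with 8.721 (8.605 to 8.619). Angptl4 was higher in control ZT20 replicate 3 with 8.785 (8.426 to 8.444) and Akr1c14 in control ZT0 replicate 3 with 7.858 (7.259 to 7.331).

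The diet difference varied over the day for 1276 genes, by a test of the difference itself. The smallest adjusted p-values were those of Trp53inp1 (1.21e-08), Foxo3 (2.37e-07), Sash1 (1.22e-06), Cyp2d22 and Slc10a6 (8.37e-06 each), Usp54, Rtn4rl2 and Tsc22d3 (9.57e-06 each), Txnip (1.01e-05) and Slc7a8 (1.21e-05). The 24 h rhythm differed between diets for 216 genes, with adjusted p-values of 0.000926 for Mag, 0.00516 for Xpo1, 0.00828 for Ezh1 and Atxn2, 0.0105 for Car5b, Enho, Anpep, Dixdc1, Emc3 and Ap1m1, and 0.023 for Bhlhe41.

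For each count 1 grouping, the real one, gave as many genes, so chance differences between mice are argued against. These groupings moved single mice, so for the rhythm counts they cannot exclude differences between collection days. At a single time the smallest share possible is 1 in 35. Over 100 groupings each, the real and the highest other counts were 1081 and 10 for rhythms on the control diet, 1731 and 111 on the high-fat diet, 216 and 3 for rhythm differences, 1180 and 84 for the average diet effect and 1276 and 259 for the interaction. Over 35 splits of the mice of a time point each, they were 365 and 10 at ZT0, 32 and 11 at ZT4, 183 and 7 at ZT8, 88 and 2 at ZT12, 1360 and 421 at ZT16 and 84 and 5 at ZT20.

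The first pattern is the large diet effect at ZT16. Further scaling by cyclic loess and by median centring gave 1387 and 1380 genes. Both started from the deposited values, already equalised by quantiles, so they cannot decide whether that normalization contributes. RNA of other cell types cannot be told apart from other changes: 46 markers of 6 other cell types had a median difference of 0.12, but they went both ways, from -1.04 to 0.88, with list medians from -0.25 to 0.30, so RNA of a single type would barely move the median over all. The count fell without any 1 of the 7 mice of ZT16, to between 1246 (without control ZT16 replicate 1) and 598 (without high-fat ZT16 replicate 3). Fewer mice also lower the power, so these falls do not decide whether a single mouse contributes. High-fat ZT16 replicate 3 had the highest mean correlation of any array with its group (0.987). Without it, 593 of the 598 genes were among the 1360. All 1360 genes kept their sign, with a median absolute log2 difference of 0.50 against 0.52. These genes were called from largely the same mice, so their signs and median do not argue against a single mouse. An earlier or sharper daily peak in high-fat mice cannot be told apart from other changes. Of the ZT16 genes, 48.8% differed the other way at ZT20 (binomial interval over genes 46.1 to 51.5). At the other times the share ran from 25.4% (ZT12) to 53.8% (ZT4). Genes are not independent replicates, so the interval is too narrow. The diet's own action at that time stays open and untested.

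The second pattern is variation between time points, in which time and collection day are confounded. Of 60 orders of the days, 16 gave as many rhythmic genes as the real order on the control diet (highest other 2050) and 5 on the high-fat diet (highest other 2054), so independent differences between days may account for these counts. For the clock list they are argued against, since 1 order, the real one, gave as high a share of variance under the 24 h curve (0.559 against 0.492). Variation outside the 24 h curve was shared by the diets, with a covariance of 0.00897, reached by 1 of 100 reassignments of the mice, the real one (highest other 0.00428). Its 12 h part exceeded the alternating part by a ratio of 2.46, which at most 84 of 720 orders reached. Orders with a negative ratio were counted as reaching it, and the 720 include the rotations and mirror images of each order. Differences between days are thus not excluded and may account for it too.

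The third pattern is the 12 named genes lower on average in high-fat mice. It was first tested on 6 of them, picked after their values per mouse had been seen (mean correlation 0.73, and -0.596 with the myofibre list), which decides nothing, and then on all 12. After group means were removed, the mean correlation between the 12 genes over 47 mice was 0.328, from -0.193 to 0.912 by pair, against 0.0593 for all 698 lower genes. The 12 include the 6 picked genes, whose pairs ran from 0.560 to 0.912, against -0.193 to 0.523 for pairs among the others. The picked genes carry much of that mean, so it does not decide whether a state that varies between mice of a group contributes. Of 7 lists compared, the myofibre list related to their mean with r = -0.553 (permutation p = 8e-05, adjusted 0.00028; rho = -0.593, permutation p = 4e-05, adjusted 0.00014; r = -0.587 without the 2 farthest mice). The endothelial list had r = -0.305 (permutation p = 0.038, adjusted 0.09) and rho = -0.393 (permutation p = 0.017, adjusted 0.04), with r = -0.243 without the 2 farthest mice. For genes that are lower, RNA of other cells gives a negative r by dilution. Dilution of the stem cells' own RNA as the only source is argued against by the satellite cell list, in a test added after its r had been seen. That list had r = -0.768 (permutation p = 1e-05, the smallest possible, adjusted 7e-05) and rho = -0.771 (permutation p = 1e-05, adjusted 7e-05), with r = -0.748 without the 2 farthest mice. Dilution beside a state that moves the 12 genes and the satellite cell list in opposite directions is not excluded. A loss of other cells that express the 12 genes would give a positive r, and the highest was 0.131, for the immune list (permutation p = 0.44). A loss of cells outside these lists was not tested and stays open.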

How the results depend on the processing

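The fits without the ZT16 mice for rhythms were chosen only after the result was seen. The cause of the changes below was not tested unless stated.

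Without a filter on dim genes, 314 genes differed at ZT8, 57 at ZT12, and 6 lists were over-represented among control rhythmic genes. With the filter at the 60th percentile, 20 genes differed at ZT4. Over all probe sets more features were tested by construction, and 2392 were rhythmic on the control and 3994 on the high-fat diet, 415 differed in rhythm, 2969 on average, 2768 in the interaction, and 812, 84, 463, 169, 3377 and 246 at ZT0, ZT4, ZT8, ZT12, ZT16 and ZT20. With the mean of a gene's probe sets, Rpl41 at ZT16 reversed to 0.0543 (adjusted p = 0.723). With cyclic loess, 6 lists were over-represented on the control diet.

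With array weights, 1932 genes were rhythmic on the control diet, 596 differed in rhythm, 2009 in the interaction, 11 at ZT4, 775 at ZT8 and 2678 at ZT16. With the replicate number as a block, 105 differed in rhythm, 56 at ZT12, and 5 lists were over-represented on the control diet. The numbers do not pair the mice, since arrays of the same number in different groups had a mean correlation of residuals of -0.0293 over 253 pairs.

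For rhythms, an F test over the 6 time points, which any difference between times can pass by construction, called 3725 control and 4115 high-fat genes. Contrasts of the 12 group means called 2044 and 2858, and 482 for the rhythm difference. A rank test called 689 and 984, the collection day as a random block 289 and 580, and fits without the ZT16 mice 1062 on the high-fat diet. Cosine and sine in place of the time factor gave 22 genes for the rhythm difference. Rhythmic genes shared by both diets numbered 204 at an adjusted p under 0.01, a stricter threshold. For the average diet effect, additive time and diet gave 784 genes and leaving out the ZT16 mice 584.

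With only the 2 groups of a time point, which leaves fewer mice to estimate the spread, limma called 86 genes at ZT0, 0 at ZT4 (991 at an unadjusted p under 0.05), 5 at ZT8, 0 at ZT12 (1363 at an unadjusted p under 0.05) and 4 at ZT20. With the correlation estimated per list, 1 list shifted with diet on average in place of 13.

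With each mouse left out in turn, counts ranged from 839 to 1126 for control rhythms, 1284 to 1791 for high-fat rhythms, 59 to 247 for rhythm differences, 969 to 1256 for the average, 837 to 1392 for the interaction, 122 to 426 at ZT0, 10 to 39 at ZT4, 58 to 215 at ZT8, 16 to 107 at ZT12, 598 to 1406 at ZT16 and 41 to 100 at ZT20. Shared rhythmic genes ranged from 397 to 514, lists over-represented from 2 to 8 (control) and 8 to 11 (high-fat), rhythmic list means from 4 to 8 and 9 to 12, and lists shifted by diet from 10 to 13. The clock list's amplitude difference ranged from 0.02 to 0.05 and its shift from -0.198 to 0.0502 h.

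Named genes gave 521 results, each a gene in a comparison, and a case is a result in a fit. Without a mouse, 153 results lost a call in 1062 cases, 3 gained a call in 10, and 0 changed sign. In 23415 cases the call stayed as it was. Under the other alternatives 245 results lost a call in 527 cases, 7 gained one in 20 and 1 changed sign, and 5174 cases left it as it was. Differences near the array's background are compressed.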

Other observations

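Genes with a 12 h component, a hypothesis formed after the data were seen, numbered 1730 on the control and 1853 on the high-fat diet, and 586 on both against 313 for independent lists. Of these 586, 476 had peaks within 2 h of each other. Of the 28 lists, 4 were over-represented among the 586 by Fisher's exact test: p53 response with 7 of 20 genes (adjusted p = 0.00216), glucocorticoid response with 5 of 14 (adjusted p = 0.0104), heat shock with 5 of 15 (adjusted p = 0.0104) and NF-kB targets with 4 of 11 (adjusted p = 0.0176). With 6 days confounded with the times, 84 of 720 orders of the days gave as high a ratio of the 12 h to the alternating part or a negative one. A 12 h rhythm may thus not be separated from day differences.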
